A study of Drosophila melanogaster with 4 samples.

How the data were processed

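RNA-seq libraries from ovaries of adult flies, 2 Control and 2 Nup358GLKD, were grouped by their labels. Per the labels' protocols, total RNA was extracted from 10 to 15 pairs of ovaries, poly(A) RNA was enriched and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, Bowtie2, RSEM and the genome build dm3 were used. Their versions, the annotation release, the strand setting and any filters are not given in the sources used here. Overlapping and antisense transcripts therefore cannot be told apart, nor can sense and antisense transposon RNA.

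The deposited table holds expected counts, which RSEM estimates per transcript and which need not be whole, per its file header and the submitters' processing notes. It has 34705 rows: 34437 RefSeq transcripts, 126 transposon families and 142 piRNA clusters. The values are not scaled for depth or length. Per library they sum to 60792292 and 59410221 in Control replicates 1 and 2 and to 58876800 and 60707552 in Nup358GLKD replicates 1 and 2, so that 3 counts, used as the floor for a count of 0, correspond to about 0.05 CPM per library. The 10 most abundant features took 5.91%, 5.87%, 7.20% and 5.91% of the counts. Transposon rows took 0.147%, 0.142%, 0.322% and 0.351%. RSEM divides reads between similar sequences, so values of related transposon families, of clusters and of near-identical genes depend on that division.

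Before testing, RefSeq rows were summed per gene with an NCBI RefSeq gene table of assembly Release 6, used for names, chromosome arms and gene order only. It matched 33997 of 34437 RefSeq rows (98.7%) to 16345 genes, and 440 unmatched rows were kept as they were. The plan written before the data were examined had said to sum transcripts where the file pairs them with genes and otherwise to test the rows as given. The file does not pair them, and the supplied table does, so summing departs from that plan. It was chosen after the row names were seen and before any test, and the results of the plan as written stand beside the main counts. Summed values were rounded to whole numbers.

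The test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust=TRUE and legacy=FALSE, glmQLFTest) on group, with TMM factors and the default filterByExpr filter (minimum count 10, minimum total 15), and Benjamini-Hochberg adjusted p under 0.05 as threshold. All adjusted p-values per gene come from this test unless another tool is named. CPM use TMM-scaled library sizes, standard errors come from the F statistic, and fitted log2 changes use a prior count of 0.125. For named genes with 12 or fewer counts in a group, the ratio of summed counts has an exact 95% interval (Clopper-Pearson, conditional on the total). Gene lists were fixed before the data were examined, except the piRNA clusters. Each was tested with camera of limma 3.58.1 (preset correlation 0.01, lists of at least 5 tested members, Benjamini-Hochberg adjusted over lists). List medians did not change when members at 0 in a group were set at their bound.

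Named genes followed a rule fixed beforehand. It takes Nup358, then the 8 largest increases and 8 largest decreases among features with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and both libraries of 1 group above both of the other. It adds up to 3 passing members with the smallest p from each list, and always piwi, aub, AGO3, vas and rhi. 1 gene that the rule takes from a list is not reported here.

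Alternatives fixed beforehand were RLE, total-count and upper-quartile scaling, DESeq2 1.42.0, limma-voom, robust=FALSE, legacy=TRUE, no filter, a mean of at least 5 CPM, glmTreat against a fold of 1.5, a replicate block and leaving out each library in turn. Where a group keeps 1 library, that library is assumed to vary like the other group's. Unsummed rows, and lists without members that their names or synonyms misplaced, were added after seeing the data. The control replicates differed by more than sampling noise (chi-square per degree of freedom 16.4) and were counted as 2 samples. The code was tested on simulated data for the comparison of Nup358GLKD with Control, over 10003 features with 50 genes changed per fold size. edgeR recovered 4% of genes changed 1.5-fold, 36% of 2-fold, 92% of 4-fold and 100% of 8-fold changes, with 9 unchanged genes called. The simulation drew genes independently and gave both groups the same spread. In the real data the SD of log2 differences was 0.158 between Control replicates and 0.606 between knockdown replicates. These rates therefore test the code and need not hold for the real libraries. Other Python steps used Python, pandas, scipy and statsmodels.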

Results

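Poly(A)-enriched RNA was sequenced from adult Drosophila melanogaster ovaries. 2 libraries were Control (the cross labelled mat>Luc) and 2 were from ovaries with a germline knockdown of the nucleoporin Nup358 (Nup358GLKD). Per the labels, each library was made from 10 to 15 pairs of ovaries. The question the series names is what Nup358 does in keeping transposons silent and in making piRNAs, the small RNAs that direct transposon silencing in the germline. The libraries held 60792292 and 59410221 expected counts in Control replicates 1 and 2, and 58876800 and 60707552 in Nup358GLKD replicates 1 and 2. The labels call the libraries biological repeats and say nothing more of separate flies, so p-values measure only the spread between these samples. Log2 CPM of the Control replicates correlated across features at Pearson's r = 0.998 with an SD of their log2 differences of 0.158, against r = 0.975 and an SD of 0.606 for the knockdown replicates. Features are not independent replicates, and these values only describe how closely the libraries resembled each other.

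Nup358 RNA was lower in both knockdown libraries than in both Control libraries. Nup358 (CG11856), a large protein of the cytoplasmic face of the nuclear pore, had 662.3 and 624.3 CPM in the Control replicates and 282.8 and 151.2 CPM in the knockdown replicates. The means were 643.3 ± 26.9 CPM in Control and 217 ± 93 CPM in Nup358GLKD (SD, n = 2 each), a 2.96-fold lower level (log2 change −1.57, SE 0.34). The knockdown replicates held 44.0% and 23.5% of the Control mean. Whole ovaries also hold somatic follicle cells, which a germline driver does not reach. The difference just missed the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0526). It passed with DESeq2 (adjusted p = 9.59e-05), without Nup358GLKD replicate 1 (log2 change −2.09, adjusted p = 8.46e-05) and without Nup358GLKD replicate 2 (−1.22, adjusted p = 0.000148), and the range over all alternatives was 8.46e-05 to 0.293.

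**Figure D1:**
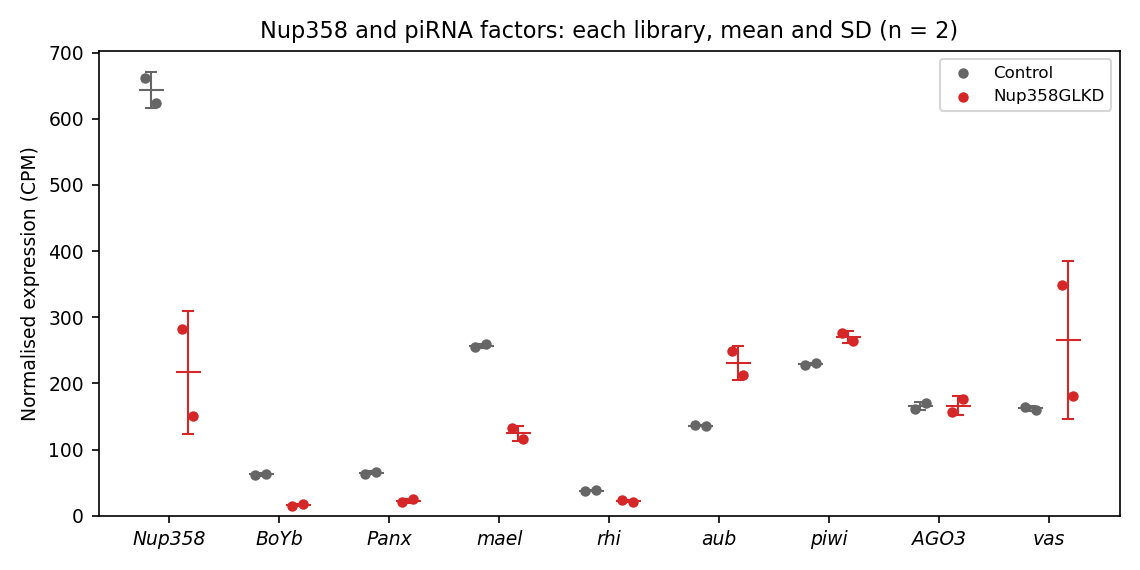
Normalised expression in CPM (vertical axis, from 0) of Nup358 and 8 piRNA pathway genes in each Control (grey) and Nup358GLKD (red) library, with horizontal marks at the group mean and bars of 1 SD (n = 2). Nup358 stood at 643.3 CPM in Control and 217 CPM in the knockdown, mael at 256.7 and 124.3 CPM, and AGO3 at about equal levels.

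Transposon RNA was more abundant in Nup358GLKD ovaries. Of 93 transposon families tested, 24 rose, 2 fell and 67 did not pass, and 29 rose and 2 fell when adjusted over the list alone. Both knockdown libraries lay above both Control libraries for 74 families, which is 79.6% of families beside 37.9% of all tested features (16.7% by chance), and the median log2 change was 1.11. All transposon rows together held 1398 ± 41.01 CPM in Control and 3467 ± 94.8 CPM in the knockdown (SD, n = 2 each), a ratio of 2.48.

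The retrotransposon accord rose from 0.845 ± 0.0917 to 25.7 ± 0.405 CPM, which was 30.3-fold (log2 change 4.92, SE 0.19, adjusted p = 0.0275). The retrotransposon diver rose 4.39-fold from 51.2 to 225 CPM (adjusted p = 0.0275), and the DNA transposon pogo rose 8.25-fold from 3.06 to 25.2 CPM (adjusted p = 0.0275). The retrotransposon blood had 0 counts in both Control libraries and 9.02 and 3.02 CPM in the knockdown libraries, at least 120-fold higher than the floor of 3 counts per library (adjusted p = 0.0453). The families that follow were chosen after their values were seen. The gypsy element rose 7.98-fold from 9.42 to 75.1 CPM, springer 9.25-fold from 19.5 to 180.4 CPM and the I-element 3.75-fold from 10.6 to 39.7 CPM. NOF fell 3.69-fold from 4.21 to 1.14 CPM and Doc2-element 4.28-fold from 1.87 to 0.438 CPM. The most abundant family, copia, had 759.2 ± 17.3 CPM in Control and 1723 ± 524 CPM in the knockdown and just missed the threshold (adjusted p = 0.0515). Without copia the summed transposon RNA was 638.4 ± 58.3 CPM in Control and 1744 ± 429.9 CPM in the knockdown, a ratio of 2.73.

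As a set the families differed from all other features in limma's camera test with a preset correlation of 0.01 (adjusted p = 1.28e-08). With the estimated correlation of 0.301 the set did not pass (adjusted p = 0.68). Nor did it pass fry, which tests a list against no change (adjusted p = 0.095). The count of 24 rested on small margins. In edgeR no family passed without Control replicate 1 or without Control replicate 2 (26 and 24 rose at an unadjusted p under 0.05), while 46 passed as higher without Nup358GLKD replicate 1 and 67 without Nup358GLKD replicate 2. With the RefSeq transcripts left unsummed, 0 of the 93 families passed in edgeR (lowest adjusted p = 0.0546) and 0 in limma-voom, 33 were higher at an unadjusted p under 0.05, 22 were higher when adjusted over the list alone, and 31 were higher in DESeq2.

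**Figure D2:**
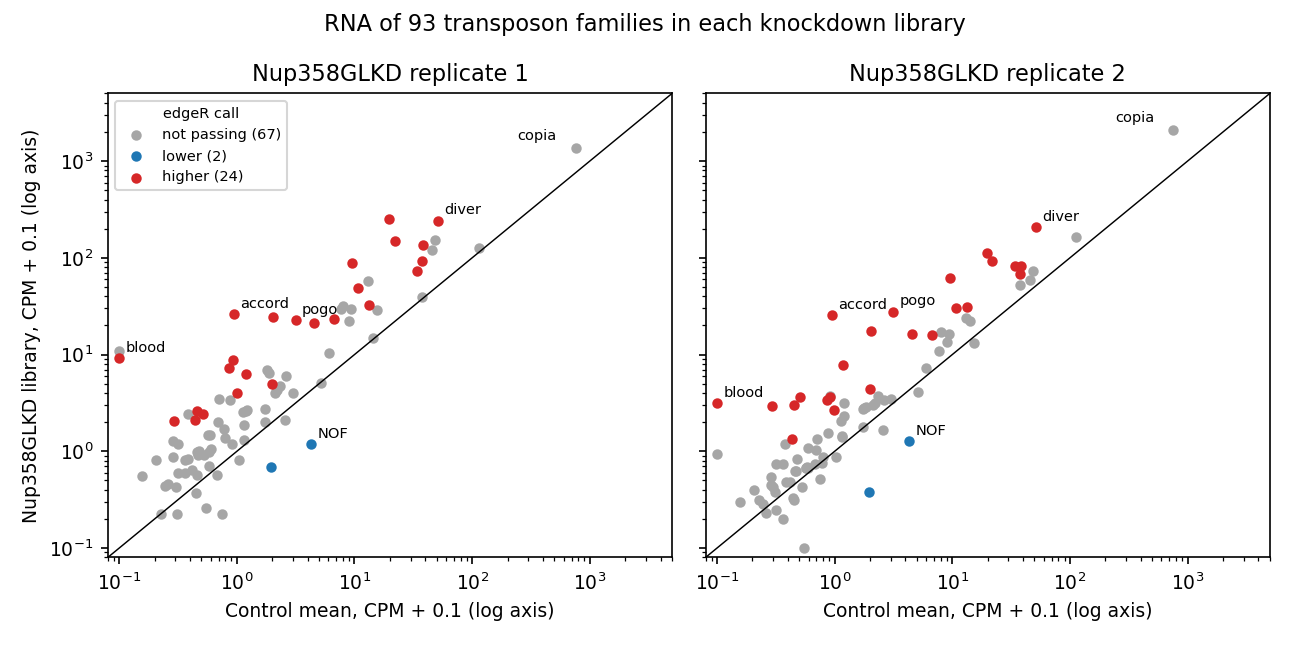
Level of each of 93 transposon families in the Control mean (horizontal, CPM + 0.1, log axis) against Nup358GLKD replicate 1 (left) and replicate 2 (right, vertical, CPM + 0.1, log axis), coloured by the edgeR call; the line marks equal levels. Most families lie above the line in both panels: 82 of 93 were above both Control libraries in replicate 1 and 76 in replicate 2.

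RNA mapped to piRNA clusters, the loci from which piRNA precursors are transcribed, was also higher in the knockdown. Of 114 tested cluster rows, 24 rose, 0 fell and 90 did not pass, and 96 had both knockdown libraries above both Control libraries (84.2%, beside 37.9% of all tested features). The median log2 change was 0.97. The somatic cluster flam rose 2.36-fold from 14.0 ± 0.117 to 33.1 ± 3.55 CPM (SD, n = 2 each, log2 change 1.24, adjusted p = 0.0289), beside a median log2 change of 1.07 over the follicle cell list. The germline cluster 42AB had 12.6 CPM in Control and 18.9 CPM in the knockdown and did not pass (log2 change 0.58, SE 0.17, adjusted p = 0.0828). The largest rises were those of cluster50, 12.7-fold from 2.38 to 30.2 CPM, and cluster53, 9.6-fold from 2.77 to 26.6 CPM, and all 4 clusters were chosen after their values were seen. The cluster set was not fixed before the data were examined. Its camera test gave p = 1.63e-11, and p = 0.27 with an estimated correlation, and fry gave p = 0.0508. Without either Control library no cluster row passed, and 49 and 87 rows rose without Nup358GLKD replicate 1 and 2. Clusters hold transposon fragments, so cluster and transposon rows can share reads. The libraries were enriched for poly(A) RNA and the strand setting is not given. These rows therefore do not measure piRNA precursors separately from other RNA of the same loci.

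Genes of the piRNA pathway went both ways. Of 36 tested members, 4 rose, 7 fell and 25 did not pass, and 6 rose and 7 fell when adjusted over the list alone. BoYb, a Tudor-domain protein of piRNA biogenesis, fell 3.86-fold from 62.4 to 16.2 CPM (log2 change −1.95, SE 0.14, adjusted p = 0.0275). Panx, which links Piwi to transcriptional silencing, fell 2.89-fold from 65.0 to 22.5 CPM (adjusted p = 0.028). The silencing factor mael fell 2.07-fold from 256.7 to 124.3 CPM (adjusted p = 0.028), and rhi, the heterochromatin protein that licenses germline clusters, fell 1.72-fold from 37.7 to 21.9 CPM (adjusted p = 0.0377, but 0.0505 at a mean of at least 5 CPM). The PIWI protein gene aub rose 1.7-fold from 135.9 to 231.1 CPM (adjusted p = 0.0379). The others, named after their values were seen, were Gasz, csul and Boot among those that fell (3.65-fold, 1.73-fold and 1.63-fold) and qin, SoYb and spn-E among those that rose (4.06-fold, 1.88-fold and 1.69-fold). The other PIWI genes did not pass: piwi had 229.4 and 270.2 CPM in Control and knockdown (adjusted p = 0.142) and AGO3 166.3 and 166.3 CPM (adjusted p = 0.999). The helicase gene vas had 162.1 and 265.4 CPM and did not pass either (adjusted p = 0.184). Its knockdown replicates lay at 349.3 and 181.5 CPM. Without Nup358GLKD replicate 1 and 2, the log2 change of vas was 0.161 and 1.08, and that of piwi 0.199 and 0.242. The list as a whole did not pass camera's test (adjusted p = 0.249).

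Among 19 tested heterochromatin and H3K9 methylation factors, 1 rose, 3 fell and 15 did not pass, and 2 rose and 6 fell when adjusted over the list alone. The SETDB1 cofactor wde fell 2.22-fold from 141.8 to 63.9 CPM (adjusted p = 0.028), HDAC1 fell 1.73-fold from 245.5 to 141.9 CPM (adjusted p = 0.0293) and the H3 kinase JIL-1 rose 2.01-fold from 127.3 to 256.6 CPM (adjusted p = 0.0329). The list median was −0.33 (camera adjusted p = 0.0262, adjusted p = 0.68 with an estimated correlation, and 0.0521 without Nup358GLKD replicate 1). Of 28 nucleoporin genes, the target included, 0 rose, 3 fell and 25 did not pass, with 10 falling when adjusted over the list alone and a median of −0.49 (camera adjusted p = 0.000827, adjusted p = 0.68 with an estimated correlation). Nup37 fell 2.61-fold from 48.6 to 18.7 CPM, Sec13 1.59-fold and Nup50 1.45-fold (adjusted p = 0.0341, 0.0347 and 0.0408). At a mean of at least 5 CPM Sec13 (0.0524) and Nup50 (0.0577) did not pass, nor did Nup50 with upper-quartile factors (0.0561) or the replicate block (0.0577). Of 32 genes of nuclear transport, Ran and SUMO, 3 rose (the mRNA export helicase Hel25E 1.63-fold, the SUMO protease velo 2.2-fold and the SUMO-conjugating enzyme lwr 1.49-fold), 1 fell and 28 did not pass, with 0 passing when adjusted over the list alone (camera adjusted p = 0.613). The call of lwr was lost with total counts (0.0627), without a filter (0.0631) and with the replicate block (0.053). Of 12 RNA interference and microRNA factors, 1 rose, 3 fell and 8 did not pass. The microRNA processing genes drosha and loqs fell 1.94-fold and 2.71-fold (adjusted p = 0.0282 and 0.0289), and AGO1 rose 1.49-fold (adjusted p = 0.0397, but 0.0537 without a filter and 0.0538 with the replicate block). Over that list alone 2 rose and 3 fell, and its median of 0.13 and mean of −0.09 differed in sign (camera adjusted p = 0.88).

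Over the whole transcriptome, many genes moved both ways. Of 10207 tested features 976 rose and 921 fell at an adjusted p under 0.05, and 768 and 501 of these changed at least 2-fold. Of 9843 genes among them, 902 rose and 914 fell. The counts carry a pair of limits. First, the file lists RefSeq transcripts without gene names, and the plan written before the data were examined called for testing the rows as given in that case. Fitted that way, edgeR called 1 of 20393 rows (a transcript of the mitochondrial channel gene porin, lower), limma-voom 0 and DESeq2 5658, while 7024 rows had an unadjusted p under 0.05. The counts given here come instead from rows summed per gene, a choice made after seeing the row names and before any test. Second, edgeR called 0 features without Control replicate 1 or without Control replicate 2 (1714 and 1548 had an unadjusted p under 0.05), and 6490 without Nup358GLKD replicate 1 and 7988 without Nup358GLKD replicate 2, so that no gene list had a passing member without either Control library. DESeq2 called 3862 features. In DESeq2 and without each library in turn, every main call with a value kept its direction, which was not compared for the unsummed rows.

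Most genes with the largest increases by the fixed rule were near 0 in Control. Ir94f, an ionotropic receptor gene, went from 9 counts over both Control libraries to 41.8 and 18.4 CPM, a ratio of 408 with a 95% counting interval of 215 to 894 (adjusted p = 0.028). The metabolic gene Pepck1 and its neighbour CG45087 rose 107-fold from 2.26 to 243 CPM (adjusted p = 0.028). Their deposited values are identical, so the 2 genes share reads and neither can be assigned the change. The transcription factor gene Lim1 rose 146-fold from 0.137 ± 0.0587 to 20.3 ± 9.18 CPM (adjusted p = 0.028). For Vajk1, MFS9 and CG15005, with 3, 3 and 9 counts over both Control libraries, the ratios were 238 (counting interval 80.9 to 1160), 361 (123 to 1750) and 67.5 (35.3 to 148). The call of CG15005 was lost in limma-voom (0.0512). Among the largest decreases were 7B2, a secretory chaperone gene, from 5.3 to 0.0872 CPM with a ratio of 61.4 (counting interval 33.2 to 129), and the gustatory receptor gene Gr61a, 27.7-fold lower from 11.4 to 0.41 CPM (both adjusted p = 0.0275). CG14567 fell 27.4-fold (adjusted p = 0.044, and 0.0546 at a mean of at least 5 CPM), CG2187 21.7-fold (0.028), the centriole gene Cep164 10.8-fold (0.0324), the cytochrome P450 gene Cyp6d4 9.82-fold from 91.5 to 9.31 CPM (0.0275), CG30046 9.6-fold (0.0275) and CG9119 9.49-fold (0.0275, all adjusted p). Intervals and floors cover counting error only. Markers of the fly strain or of construct backgrounds differed too: of 5 such genes 3 rose, 0 fell and 2 did not pass, with 3 rising when adjusted over the list alone. The cuticle pigment gene y rose 8.13-fold from 2.6 to 21.2 CPM (adjusted p = 0.028), ry had a ratio of 11.8 (counting interval 4.76 to 37.7, adjusted p = 0.0311), and sc had 0 counts in Control and was at least 11-fold higher (adjusted p = 0.0376). That list had camera adjusted p = 0.0188, adjusted p = 0.68 with an estimated correlation, and 0.118 and 0.0533 without Nup358GLKD replicate 1 and 2.

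Proteasome subunit genes were lower as a group. Of 36 tested members 0 rose, 19 fell and 17 did not pass, and 31 fell when adjusted over the list alone. All 36 had a negative log2 change, with a median of −0.62. Prosalpha7 of the core particle fell 2.21-fold from 328.8 to 149 CPM (log2 change −1.14, SE 0.11, adjusted p = 0.028), and Rpn1 and Rpn2 of the regulatory particle each fell 1.76-fold (adjusted p = 0.0301 and 0.0302). The camera adjusted p was 4.35e-09, and the adjusted p = 0.68 with an estimated correlation. Ribosomal protein genes were higher as a group, though few passed singly. Of 89 genes that the list took by name, 10 rose, 0 fell and 79 did not pass, and 59 rose when adjusted over the list alone. The list holds Sam-S, an enzyme gene taken through a synonym, and 3 genes with names ending in -like. Without these 4, left out after seeing the data, 7 of 85 rose, 0 fell and 78 did not pass, 56 rose when adjusted over the list alone, and the median was 0.68 (camera adjusted p = 2.5e-11, adjusted p = 0.689 with an estimated correlation). RpL14 rose 1.98-fold from 936.9 to 1852 CPM (adjusted p = 0.0401), RpL37-1 2.04-fold (adjusted p = 0.0408) and RpLP0-like, 1 of those left out, 2.69-fold (adjusted p = 0.0361). With all 89 the camera adjusted p was 8.49e-12, and 88 of them were higher in Nup358GLKD replicate 1 than in replicate 2. Without the 4, the median log2 ratio to the Control mean was 0.853 in replicate 1 and 0.473 in replicate 2. Of 73 mitochondrial ribosomal protein genes 1 rose (mRpS30, 1.44-fold, not passing with total counts, without a filter or with the replicate block), 2 fell (mRpL54 1.71-fold and mRpL45 1.63-fold) and 70 did not pass, with 0 when adjusted over the list alone. Their median was −0.17 (camera adjusted p = 0.0262, adjusted p = 0.68 with an estimated correlation, 0.0719 and 0.0791 without Control replicate 1 and 2).

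The JNK and JAK-STAT list holds targets and components of these stress pathways. Of 15 tested, 8 rose, 0 fell and 7 did not pass, and 10 rose when adjusted over the list alone. The matrix metalloproteinase genes Mmp1 and Mmp2 rose 6.66-fold from 2.56 to 17.1 CPM and 4.97-fold from 12.1 to 60 CPM (adjusted p = 0.0275 and 0.028), and chinmo, a transcription factor gene of stem cells, rose 10.0-fold from 1.39 to 14.0 CPM (adjusted p = 0.028). The median was 0.96 (camera adjusted p = 0.00071, adjusted p = 0.68 with an estimated correlation). DNA damage and apoptosis genes were divided: of 32, 8 rose, 4 fell and 20 did not pass, and 9 rose and 9 fell when adjusted over the list alone. The stress transcription factor gene Xrp1 rose 2.76-fold from 75.2 to 207.4 CPM, Gadd45 4.63-fold from 8.01 to 37.1 CPM and the TNF ligand gene egr 2.65-fold from 8.33 to 22.1 CPM (each adjusted p = 0.028). That list's median of −0.32 and mean of 0.03 differed in sign (camera adjusted p = 0.532). Of 22 ER stress and ATF4 target genes 2 rose, 5 fell and 15 did not pass, and 3 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.299). Atf3 rose 3.49-fold from 6.9 to 24.1 CPM, the serine synthesis gene CG11899 fell 2.56-fold and the kinase gene PEK fell 1.63-fold (adjusted p = 0.028, 0.028 and 0.0332). Of 23 heat shock and proteostasis genes 1 rose (the co-chaperone gene stv, 5.73-fold, adjusted p = 0.028), 0 fell and 22 did not pass, with 1 rising when adjusted over the list alone (camera adjusted p = 0.221). Of the 23, 16 had a positive log2 change. The Control replicates differed for Hsp70Ab, chosen after its values were seen, at 44.69 and 185.5 CPM. Its knockdown replicates lay at 624.3 and 326.8 CPM, and it did not pass (adjusted p = 0.131).

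Immune genes included 4 that rose, 0 that fell and 17 that did not pass of 21, with 4 rising when adjusted over the list alone. Tep4 rose 3.94-fold from 24.6 to 97.0 CPM and pirk, an inhibitor of the IMD pathway, 5.87-fold (adjusted p = 0.0317 and 0.0427). The call of pirk was lost in limma-voom (0.056). PGRP-LF, with 12 counts in Control, had a ratio of 11 (counting interval 6.07 to 21.8, adjusted p = 0.0347). The median was 0.78 (camera adjusted p = 0.0111, adjusted p = 0.68 with an estimated correlation, 0.0804 without Nup358GLKD replicate 2). TotA, the 1 tested member of 8 Turandot stress genes, rose from 8 to 36 counts, a ratio of 4.82 (counting interval 2.2 to 12, adjusted p = 0.05 after rounding, just under the threshold), and did not pass with RLE factors (0.0501), with total counts (0.0502), without a filter (0.0652), with the replicate block (0.0779), in DESeq2 (0.107) or without Nup358GLKD replicate 1 (0.0593). Of 31 glutathione S-transferase genes 4 rose, 6 fell and 21 did not pass, and 9 rose and 13 fell when adjusted over the list alone. GstE10 had 1 count in Control and a ratio of 383 (counting interval 68.2 to 15200, adjusted p = 0.0275), while GstD3 fell 3.57-fold from 449.4 to 126 CPM and GstE13 2.38-fold (adjusted p = 0.0293 and 0.0281). The median of 0.12 and camera's direction differed in sign (adjusted p = 0.684). Of 66 genes that the cytochrome P450 list took by name 3 rose, 4 fell and 59 did not pass, with 3 rising and 4 falling when adjusted over the list alone. Of these, Cyp1 and Cyp40 are cyclophilin genes and did not pass, which leaves 64 cytochrome P450 genes, of which 57 did not pass. Cyp311a1 fell 7.33-fold and Cyp4d8 rose 3.55-fold (adjusted p = 0.0315 and 0.0316). The median of the 64, chosen after seeing the data, was 0.86 (camera adjusted p = 0.0355 and 0.042 with all 66, adjusted p = 0.68 with an estimated correlation, and 0.313, 0.131 and 0.291 without Control replicate 1, Control replicate 2 and Nup358GLKD replicate 2). Of 20 ecdysone pathway genes 3 rose, 0 fell and 17 did not pass, with 3 rising when adjusted over the list alone: shd and spo, enzymes of ecdysone synthesis, rose 3.16-fold and 2.23-fold, and Eip93F 3.46-fold (adjusted p = 0.0337, 0.0381 and 0.0351). The list's camera adjusted p was 0.108, and 0.0457 without Nup358GLKD replicate 2.

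Most germline genes did not pass the test. Of 35 germline and oocyte genes 6 rose, 0 fell and 29 did not pass, with 6 rising when adjusted over the list alone and a median of 0.19 (camera adjusted p = 0.178). The translation regulator gene orb rose 2.69-fold from 709.3 to 1908 CPM, the gap junction gene zpg 2.2-fold from 223.8 to 492.5 CPM and Pabp2 2.65-fold from 139.7 to 370.3 CPM (adjusted p = 0.0293, 0.028 and 0.028). Of 27 genes of germ cell differentiation and meiosis 2 rose, 4 fell and 21 did not pass, and 5 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.512). The crossover gene mei-218 fell 1.81-fold from 53.8 to 29.8 CPM, and c(3)G of the synaptonemal complex rose 1.88-fold from 27.5 to 51.7 CPM (adjusted p = 0.0318 and 0.0332). Of 27 follicle cell genes 4 rose, 1 fell and 22 did not pass, and 5 rose and 1 fell when adjusted over the list alone. The adhesion gene Fas3 rose 3.25-fold from 46.6 to 151.6 CPM, ImpL2 3.08-fold and the EGF receptor inhibitor gene aos 2.48-fold (adjusted p = 0.0275, 0.0311 and 0.0318). Their median was 1.07 (camera adjusted p = 0.00071, adjusted p = 0.689 with an estimated correlation), with 1.34 in Nup358GLKD replicate 1 and 0.53 in Nup358GLKD replicate 2, and 23 of the 27 were higher in replicate 1 than in replicate 2. Of 9 yolk protein and uptake genes 1 rose, 1 fell and 7 did not pass, with 1 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.599): cv-d rose 4.3-fold and the yolk protein gene Yp3 fell 2.89-fold from 1271 to 439.9 CPM (adjusted p = 0.0302 and 0.0402). The yolk protein genes Yp1 and Yp2, named after their values were seen, lay higher in the knockdown but did not pass. Yp1 had 3209 CPM in Control and 5112 CPM in the knockdown, and Yp2 3504 and 5393 CPM (adjusted p = 0.0907 and 0.109).

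Genes on the eggshell list and on the cell cycle list differed between the knockdown replicates. Of 25 genes on the vitelline membrane and chorion list, most of which follicle cells express while building the eggshell, 1 rose, 0 fell and 24 did not pass, with 1 rising when adjusted over the list alone. That 1 was pip, a dorsoventral patterning sulfotransferase and not a shell protein, 4.63-fold from 5.38 to 24.9 CPM (adjusted p = 0.028). The list's median log2 ratio to the Control mean was −2.05 in Nup358GLKD replicate 1 and −0.09 in Nup358GLKD replicate 2. The list also holds Grip, taken through a synonym and not an eggshell gene, which did not pass. Without it the medians were −2.07 and −0.10 and the camera adjusted p was 0.0649, a check chosen after seeing the data. With it the camera adjusted p was 0.0858, and it was 0.0209 without Control replicate 1, 0.0083 without Control replicate 2 and 1.05e-06 without Nup358GLKD replicate 2, each toward lower levels. Without Nup358GLKD replicate 1 the direction turned to higher (adjusted p = 0.981), and an estimated correlation gave adjusted p = 0.758. Of 41 cell cycle and replication genes 0 rose, 4 fell and 37 did not pass, with 0 when adjusted over the list alone. The chromatin assembly gene Caf1-180 fell 1.67-fold, Dp 1.86-fold and CycE, which drives S phase entry, 3.74-fold from 375.7 to 100.5 CPM (adjusted p = 0.0374, 0.0376 and 0.0417). Medians were −1.25 and −0.33 in Nup358GLKD replicates 1 and 2 (camera adjusted p = 2.31e-05, adjusted p = 0.689 with an estimated correlation). Of 70 histone genes 3 rose, 2 fell and 65 did not pass, the same counts as adjusted over the list alone. The replication-independent genes His4r and His3.3B rose 2.02-fold from 186.8 to 376.7 CPM and 2.19-fold from 548.9 to 1205 CPM (each adjusted p = 0.028). Of the 70 rows, 47 have the same 4 values as another row, so they count the same reads repeatedly and no median or set test of the list is given. Replication-dependent copies such as His2B:CG33906, with a ratio of 62.7 (counting interval 24.2 to 232) toward lower levels, share reads with near-identical copies and are uncertain.

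**Figure D3:**
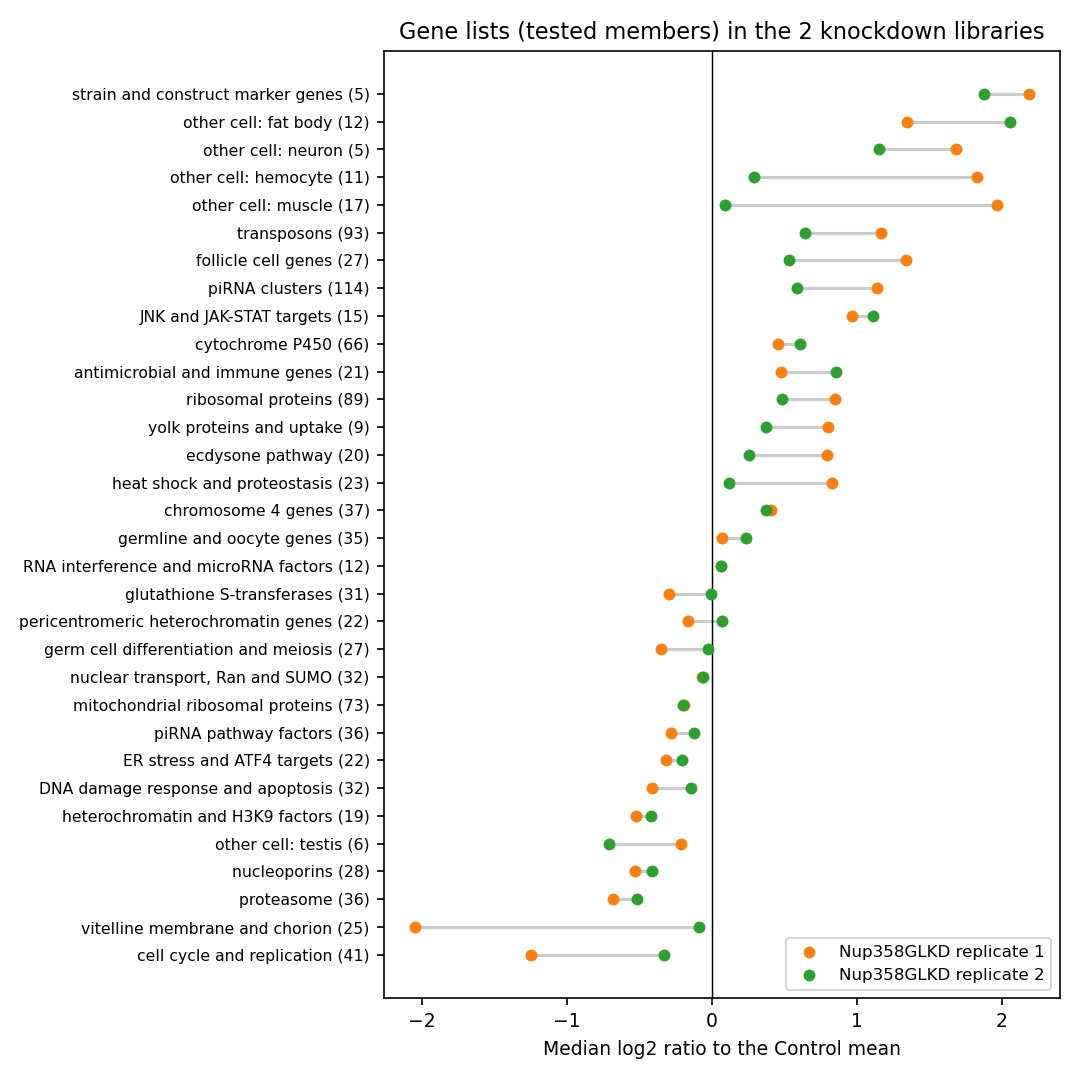
Median log2 ratio to the Control mean (horizontal axis) of the tested members of each gene list with at least 5 tested members, other than the histones. The number of members is in parentheses, and medians are shown for Nup358GLKD replicate 1 (orange) and replicate 2 (green). Transposons lay at 1.16 and 0.64, eggshell genes at −2.05 and −0.09, and muscle markers at 1.97 and 0.09.

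Of 37 tested genes of chromosome 4, a largely heterochromatic chromosome, 7 rose, 1 fell and 29 did not pass, and 13 rose and 2 fell when adjusted over the list alone. The Wnt effector gene pan rose 3.08-fold from 19.1 to 59.0 CPM, Zyx 1.83-fold and myo 1.66-fold (adjusted p = 0.0275, 0.0312 and 0.0329). The median was 0.40 (camera adjusted p = 0.0181, adjusted p = 0.68 with an estimated correlation, and 0.105, 0.0791 and 0.108 without Control replicate 1, Control replicate 2 and Nup358GLKD replicate 2). Of 22 genes in pericentromeric heterochromatin 1 rose (RpL38, 1.72-fold), 1 fell (Parp1, 1.43-fold) and 20 did not pass, with 0 when adjusted over the list alone. RpL38 did not pass without a filter (0.0529), and Parp1 did not pass without a filter (0.0529), with upper-quartile factors (0.0599), at a mean of at least 5 CPM (0.0598) or with the replicate block (0.0645). The list's median of −0.07 and mean of 0.03 differed in sign (camera adjusted p = 0.874). Of 9 Y chromosome genes in the file, 0 had enough counts to be tested.

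Fat body markers rose in part, while most markers of other cells outside the ovarian follicles did not pass. Of 12 fat body markers 4 rose, 0 fell and 8 did not pass, and 10 rose when adjusted over the list alone. The storage protein gene Lsp2 rose 34-fold from 0.501 to 17.1 CPM, tobi rose 12-fold, and fit rose from 3 and 1 counts in the Control libraries to 58 and 149 counts in the knockdown libraries (adjusted p = 0.028, 0.028 and 0.0313). Fat body medians were 1.35 and 2.06 in Nup358GLKD replicates 1 and 2 (camera adjusted p = 0.000527, adjusted p = 0.68 with an estimated correlation, 0.0541 without Nup358GLKD replicate 2). Of 17 muscle markers 1 rose (Zasp52, 1.84-fold, adjusted p = 0.0403), 0 fell and 16 did not pass, with 0 when adjusted over the list alone. Their medians were 1.97 and 0.09 (camera adjusted p = 0.0167, adjusted p = 0.689 with an estimated correlation, 0.233 without Nup358GLKD replicate 1). Of 11 hemocyte markers 1 rose (ush, 2.6-fold, adjusted p = 0.0398), 0 fell and 10 did not pass, with 0 when adjusted over the list alone. Their medians were 1.83 and 0.29 (camera adjusted p = 0.0262, adjusted p = 0.689 with an estimated correlation, 0.233 without Nup358GLKD replicate 1). Of 5 neuron markers 1 rose (elav, 2.92-fold, adjusted p = 0.0409), 0 fell and 4 did not pass, with 3 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.249). Of 6 testis markers 0 rose, 1 fell (tbrd-1, from 55 to 8 counts, ratio 6.41, counting interval 3.04 to 15.6, adjusted p = 0.0358, and 0.0527 with the replicate block) and 5 did not pass, with 1 falling when adjusted over the list alone (camera adjusted p = 0.271). None of 3 gut and 4 reproductive tract markers passed, with 3 gut markers rising when adjusted over the list alone, and both lists were too short for the set test.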

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

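The settings were chosen before the data were examined except the unsummed rows, the lists without misplaced members and the tests of Nup358, transposon and cluster counts under each setting, which were chosen after. No named gene reversed. In the 15 settings on summed features all main calls with a value kept their direction; unsummed rows were not compared. The balance of calls turned, from 976 higher and 921 lower to 894 and 1047 with total counts and 917 and 1015 in limma-voom. Of 103 named genes other than Nup358, 100 passed in the main fit. The calls lost were 1 with RLE factors, 3 with total counts, 2 with upper-quartile factors, 1 in DESeq2, 2 in limma-voom, 6 without a filter, 5 at a mean of at least 5 CPM (86 of the 103 tested), 7 with the replicate block, 69 with glmTreat, 1 without Nup358GLKD replicate 1 and all 100 without Control replicate 1 or 2. Upper-quartile scaling moved the median log2 change of all features from 0.01 to 0.14 and the share of higher calls from 51.4% to 61.6%, and total counts to −0.08 and 46.1%. DESeq2 called 3862 features (1830 higher, 2032 lower), 41 transposon families and 38 clusters as higher. glmTreat against a fold of 1.5 called 189 (136 higher, 53 lower), 7 families and 3 clusters, since it asks for a larger change. A mean of at least 5 CPM left 717 features higher and 609 lower, and 15 families and 13 clusters higher, with fewer features tested. Unsummed rows gave 1 call (0 higher, 1 lower) and 0 transposon families. There 20393 rows were adjusted for in place of 10207 features, and the lowest transposon adjusted p moved from 0.0275 to 0.0546. Families higher at an unadjusted p under 0.05 also fell from 45 to 33, and over the list alone from 29 to 22, so the number of rows is not the only cause. Other causes were not tested. Leaving out 1 library gave 0 to 7988 calls (higher 0 to 3773, lower 0 to 4215), 0 to 67 transposon families and 0 to 87 clusters. The low ends come from leaving out a Control library, when the spread rests on the knockdown pair alone, and the high ends from leaving out a knockdown library, when it rests on the Control pair alone.

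The log2 change of Nup358 passed with total counts (−1.67, adjusted p = 0.0419), in DESeq2 (−1.60, 9.59e-05), with robust=FALSE (−1.57, 0.0486) and with the replicate block (−1.64, 0.0295), and ranged from −2.09 to −1.22 without 1 library. Which pair of libraries sets the spread decides the call there, and for the other settings the cause was not tested. The replicate block called 2361 features. Deviations of same-numbered libraries from their group means correlated at 0.27 over features, and with 2 pairs and no label of a shared day the libraries share only a number. Of 32 fixed lists tested, 17 passed camera with a preset correlation (1 of them the histones, whose rows repeat the same reads), 0 with an estimated correlation and 8 with fry, which tests each list against no change. The transposon (adjusted p = 0.095), proteasome (0.0521) and ribosomal protein (0.153) lists did not pass fry. Depth, at 58876800 to 60792292 counts per library, limits genes near 0. For other genes the calls depended on which pair of libraries set the spread. How far the number of libraries limits them was not tested.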

Other observations

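The tests of why transposon RNA was higher, those of why the knockdown replicates differed, and the way neighbouring genes were counted and draws matched were chosen only after the result was seen. Those of transposon classes, chromosome arms and neighbouring genes were fixed before.

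Transposon classes rose by similar amounts. Of 42 tested LTR families 14 rose and 0 fell, with a median log2 change of 1.24. Of 29 non-LTR families 5 rose and 1 fell (median 1.00), and of 22 DNA transposon families 5 rose and 1 fell (median 1.04). The hypothesis that the classes rose by different amounts was not borne out, since a spread of medians of 0.24 or more arose often when class names were permuted over families (permutation test, p = 0.74). Families are not independent replicates, and a small difference between classes was not excluded.

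Transposon and cluster RNA was higher in both knockdown libraries. The hypothesis that 1 library alone carries the rise is argued against by Nup358GLKD replicate 2. Its median transposon log2 ratio was 0.642 (bootstrap 95% interval over families 0.49 to 0.87), beside 1.164 in replicate 1. Cluster medians were 0.588 in replicate 2 and 1.138 in replicate 1. By these medians the rise was larger in replicate 1, which kept more Nup358 RNA (44.0% of the Control mean) than replicate 2 (23.5%). Summed transposon RNA did not follow that order, at 3400 CPM in replicate 1 and 3534 CPM in replicate 2. Without copia the sums were 2048 and 1440 CPM. A loss of late egg chambers could enrich other RNA. The transposon median exceeded that of the germline and oocyte list by 1.097 in replicate 1 and 0.41 in replicate 2 (interval 0.235 to 0.812). That list stood at 0.067 in replicate 1, where the eggshell median was −2.049, and at 0.232 in replicate 2, where it was −0.086. The list did not rise where eggshell RNA fell, so it cannot show what such a loss would do to other germline RNA. Background reads such as genomic DNA would lift silent genes. Over 2465 protein-coding genes at 0 in both Control libraries, the 90th percentile reached at most 0.0539 CPM. Median gains were 18.2 and 13.6 CPM in replicates 1 and 2 for the 24 families that rose. Those families were picked for rising, and the number of copies per family was not taken into account. The comparison therefore cannot exclude background, least of all for families with small gains such as INE-1 (0.454 and 0.0657 CPM). Follicle cell genes, which are somatic, moved in the same order as the transposon medians, with medians of 1.342 in replicate 1 and 0.532 in replicate 2. What raised transposon RNA stays open. Background reads and a loss of late egg chambers were not excluded. A different set of transposon copies in the parental strains and a change in the ratio of germline to somatic cells were untested. No test here separates these explanations from an effect of the knockdown on silencing.

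The knockdown replicates differed from each other. Chorion genes were lower in replicate 1 than in replicate 2 by a median of −1.984 (9 of 9 genes) and vitelline membrane genes by −1.81 (8 of 8), while the germline list differed by −0.07, a pattern consistent with a different mix of egg chamber stages in the 2 samples. A mislabelled Control is argued against by Nup358, at 44.0% of the Control mean in replicate 1 and 23.5% in replicate 2. If a lower share of ovarian tissue raised markers of all other cells alike, muscle and fat body markers would move together. They moved apart by 2.695 log2 units between the replicates, muscle being higher and fat body lower in replicate 1. Hemocyte markers and follicle cell genes were also higher in replicate 1, by medians of 2.181 and 0.749. The markers do not tell whether muscle RNA came from within the ovary, so a lower share of egg chambers in replicate 1 stays open. Tissue carried along in dissection and a stronger effect on oogenesis in replicate 1 remain untested, and replicate 1, with the larger eggshell change, kept more Nup358 RNA than replicate 2.

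Genes with an 8-fold or larger change may partly mark different genetic backgrounds of the parental strains. None of the 6 chromosome arms tested held an excess of the 227 such protein-coding genes (198 higher, 29 lower), with a largest odds ratio of 1.2 on 2R (Fisher's exact test, adjusted p = 0.729). With genes of identical values counted once, 226 remained, with 28 adjacent pairs. Adjacent here means consecutive among the tested protein-coding genes of an arm, at any distance, so other genes may lie between the members of a pair. Subsamples of 195 of them held a median of 19 pairs, against a median of 9 in 10000 draws of 195 smaller-fold calls matched on direction and level (p = 0.0016), and shuffling the fold classes among all matched calls gave p = 0.0002 (permutation tests). In each of these pairs both genes moved the same way, among them y with sc, MtnB with MFS9 and Pvf2 with Pvf3. Blocks of strain difference are a candidate explanation, and so are shared regulation of neighbouring genes, including gene families such as Gr59e with Gr59f, and reads shared between neighbours, as Pepck1 and CG45087 share theirs. These data do not separate them.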
